A study of Caenorhabditis elegans with 16 samples.

How the data were processed

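RNA was sequenced from whole bodies of Caenorhabditis elegans collected on day 1 of adulthood. Per the labels' protocols, worms were fed HT115 bacteria that carry the L4440 vector and make double-stranded RNA of a chosen gene (RNAi by feeding), total RNA was purified on columns, and libraries were made with standard Illumina protocols. The labels do not say whether the libraries kept the strand of the RNA, whether transcripts were selected by their poly(A) tail, or whether reads were single or paired. The 16 libraries form 4 groups of 4, and the titles number the libraries of each group from 1 to 4. TU3401, as known from the field, is a strain that lacks the double-stranded RNA channel SID-1 except in neurons, so that feeding RNAi acts mainly in neurons. The first group is TU3401 fed the RNAi that the labels call Luc. The other groups carry in addition a glp-1 mutation, which removes the germline, and were fed Luc RNAi (the control here), mml-1 RNAi or mxl-2 RNAi. The labels do not say whether the replicates came from separate cultures. The p-values therefore measure only the spread between these libraries, which may in part be technical.

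Per the labels, the authors deposited 3 tables, each setting 2 groups side by side, with RPKM values (reads scaled to gene length and library size) for each library. Per the file headers, the authors also deposited a log2 fold change, a p-value and a false discovery rate per gene for each of the 3 comparisons, and the tables' names credit these to edgeR. The submitters' processing notes name bcl2fastq, TopHat2 version 2.1.1 and the genome build GRCh38. GRCh38 is a human build, while the tables hold worm gene names, so the build used for these values is not given in the sources used here. The counting tool is not given either. The columns of the control group are the same in all tables that share them (largest difference 0.0), so the 3 tables are on 1 scale. Each table has 42048 genes and other loci, of which 16716 were at 0 in all libraries. Names were matched to the Ensembl release 115 annotation of WBcel235, 38305 by symbol, 1423 by sequence name, and 2320 not at all. All coordinates are from that annotation. Of the names, 11 had been turned into dates, of which 9 were tested but are never named. The tables list 13384 piRNA loci, whose 21-base length makes 1 read worth about 2 RPKM.

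RPKM values are no counts, so the main test ran on a log scale. Because the authors deposited RPKM with many digits, the whole reads behind the values could be worked out. All 25332 genes above 0 came out as whole reads within a tolerance of 0.001, with 1 length per gene and 1 total per library. The gene lengths found in this way match coding sequence (91.9% are multiples of 3 among coding genes), so they are coding lengths. The recovered totals ran from 18818680 to 27228111 reads. These reads served for an alternative test and for statements on depth. For a gene of 1 kb, 1 read was worth 0.0367 to 0.0531 RPKM. Reads without molecular identifiers are not independent molecules, so floors given from reads cover counting error only. A group whose 4 libraries held no read of a gene was given a floor of 3 reads over the group.

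Tests ran in R 4.3.3 with limma 3.58.1. Values were log2(RPKM + 1), genes needed a mean RPKM of at least 1 over the 8 libraries of a comparison, and only those 8 libraries were fitted (lmFit, then eBayes with trend and robust variances, 2-sided). A gene was called when its Benjamini-Hochberg adjusted p was under 0.05. All log2 fold changes are on this scale, which understates the change of genes with few reads. The comparisons were glp-1 against TU3401, mml-1 RNAi against control RNAi, mxl-2 RNAi against control RNAi (all 3 as the authors paired them), and mxl-2 RNAi against mml-1 RNAi. The overlap of the knockdowns and the reversal of the glp-1 difference were measured as counts, correlations and covariances over genes, which are not independent replicates. Both measures share the control libraries between the differences compared, so each is given beside 100 simulations in which groups did not differ, and again with the controls split between the comparisons. The simulations drew every gene and library independently, with each gene's spread within groups. They hold no pairing by number, and their ranges leave out spread that genes share. The choice of tests, gene lists, rule for named genes and the alternatives named first below was made before the data were examined.

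The 26 gene lists were oocyte and germline, meiosis, sperm, DNA replication and cell cycle, early embryo zygotic genes, somatic gonad, neuron, neuropeptide and insulin-like peptide, muscle, intestine, hypodermis and collagen, vitellogenin, DAF-16 target, germline longevity regulator, Myc and Mondo network, autophagy, lysosome, heme peroxidase, peroxide removal and thiol redox, glutamate transport and metabolism, glutamate receptor, fatty acid metabolism, innate immunity, xenobiotic detoxification, heat shock and unfolded protein response, and ribosomal protein. The lists come from general knowledge of the worm, not from these libraries. They were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists with at least 5 measured members. Alternatives were an estimated correlation and limma's fry, which asks whether the members of a list move one way on balance and does not compare them with other genes. A list is said to have risen or fallen only where camera's adjusted p was under 0.05.

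Named genes were fixed by rule. They are the genes of the design (mml-1, mxl-2, glp-1, sid-1, glt-5, mlt-7, lgg-1, hlh-30, daf-16), the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap and whose higher mean was at least 2 RPKM, and up to 4 members of each list with the lowest p-values, of which about 20 to 30 are given per comparison. For a largest rise or fall, the rule of no overlap fixes that all 4 pairs go the same way, so the count of pairs adds no support. Genes outside the rule were chosen after their values were seen and are said to be so. Genes with near-identical copies (major sperm proteins, vitellogenins, some collagens, heat shock proteins and glycosyltransferases) are uncertain, because the sources do not say how shared reads were counted, and overlapping or antisense genes are uncertain because the strand is not known.

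The replicate numbers were checked for pairing. Deviations from the group means of same-numbered libraries correlated over genes at 0.160, 0.241, 0.120 and 0.265 for numbers 1 to 4 in glp-1 against TU3401, at 0.614, 0.501, 0.291 and 0.569 for mml-1 RNAi, at 0.637, 0.199, 0.394 and 0.488 for mxl-2 RNAi, and at 0.611, 0.217, 0.463 and 0.676 between the knockdowns. Every one was over 0.1, the bound used here, so the numbers were taken to pair the libraries. For number 3 in glp-1 against TU3401 the best correlation with another number (0.240) was above its own, and for number 3 of mml-1 RNAi it was 0.270, close to its own. This pairing comes from the data, since the labels say nothing on shared days or batches. In the 12 glp-1 libraries the leading principal component held 33.9% of the variance, and the replicate number accounted for 94.4% of that component. The planned test had no block for the replicate number, and the fit with such a block is given beside it for the counts of genes and lists called and for named genes whose call it changes. Without the block, differences between numbers stay in the error, so that test is cautious where the numbers pair the libraries. No 2 libraries of a group were the same within counting noise (lowest chi-square per degree of freedom between replicates 9.63).

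The fits were tested on simulated libraries in which 2-fold and 4-fold changes were set. Without the block, the 4-fold changes found were 87.9% for glp-1 against TU3401 (12624 genes), 88.3% for mml-1 RNAi (12325 genes), 92.9% for mxl-2 RNAi (12338 genes) and 85.3% between the knockdowns (12329 genes). The 2-fold changes found were 68.5%, 51.5%, 68.1% and 52.0%, in the same order. All had the right direction, and 16 of 159, 12 of 145, 6 of 162 and 6 of 138 calls were false. With the block, the 4-fold changes found were 79.1%, 79.8%, 77.8% and 80.0%, the 2-fold changes 52.2%, 35.1%, 43.6% and 34.7%, and 11 of 131, 8 of 117, 6 of 124 and 6 of 116 calls were false. The simulated libraries were drawn independently, with no effect of the replicate number. These shares therefore do not show which fit finds more in paired libraries.

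Alternatives covered the pseudocount (0.1 and 5), the filter (none, or a mean of at least 5 RPKM), quantile and median-ratio scaling, limma without trend, the replicate block, all 4 groups in 1 fit, a minimum log2 fold change of 1, the authors' deposited false discovery rates, and leaving out each library in turn. Further ones, chosen after seeing the data, were limma's voom on the recovered reads, genes of at least 200 bases (which leaves out piRNA loci), combinations of these with the block, and smaller sets of libraries matched by number.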

Results

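Whole-body RNA of day 1 adults was profiled in 16 libraries, 4 per group. The groups were TU3401 worms on Luc RNAi, as the labels call it, and germline-less glp-1 worms of the same neuron-RNAi background on Luc RNAi (the control), mml-1 RNAi or mxl-2 RNAi. MML-1 and MXL-2 are partner transcription factors of the Mondo and Mlx family. The totals recovered from the deposited values were 18818680, 23323166, 22570249 and 25743074 reads in TU3401 replicates 1 to 4, and 21303724, 23298892, 23669755 and 27228111 in the glp-1 control. They were 19263484, 22970035, 23046968 and 25139007 reads in the libraries labelled mml-1 RNAi and 23667131, 19242986, 24315411 and 21725100 in those labelled mxl-2 RNAi. Across all 16 libraries the leading principal component held 89.4% of the variance. The group accounted for 99.96% of that component.

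The knockdown targets were examined first. Reads of mml-1 (chromosome III, 7370130 to 7374731) stood at 23.8, 91.5, 28.9 and 22.9 RPKM in the libraries labelled mml-1 RNAi, replicates 1 to 4, against 35.2, 23.95, 11.9 and 11.24 RPKM in the glp-1 control. The means were 41.8 ± 33.3 and 20.6 ± 11.4 RPKM (SD, n = 4 each; limma adjusted p = 0.819). Reads of mxl-2 (chromosome III, 186949 to 188131) stood at 29.3, 90.7, 733 and 47.4 RPKM in the libraries labelled mxl-2 RNAi, against 24.5, 30.3, 20.99 and 22.9 RPKM in the control, and all 4 pairs of the same number were higher. The means were 225 ± 340 and 24.7 ± 4.003 RPKM (SD, n = 4; limma adjusted p = 0.766). In the authors' deposited table the rise of mxl-2 in that comparison had a false discovery rate of 0.0107. The library labelled mml-1 RNAi replicate 3 held 308 RPKM of mxl-2, while the other 3 of its group held 25.4 to 26.98 RPKM. A lower target level was therefore not seen in either knockdown group, and the groups are named by their labels throughout. Feeding RNAi acts mainly in neurons in this background, and the RNA came from whole bodies. A fall confined to neurons could therefore go unseen. In the TU3401 libraries mml-1 stood at 13.96 ± 1.76 RPKM and mxl-2 at 81.2 ± 2.34 RPKM (SD, n = 4).

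**Figure D1:**
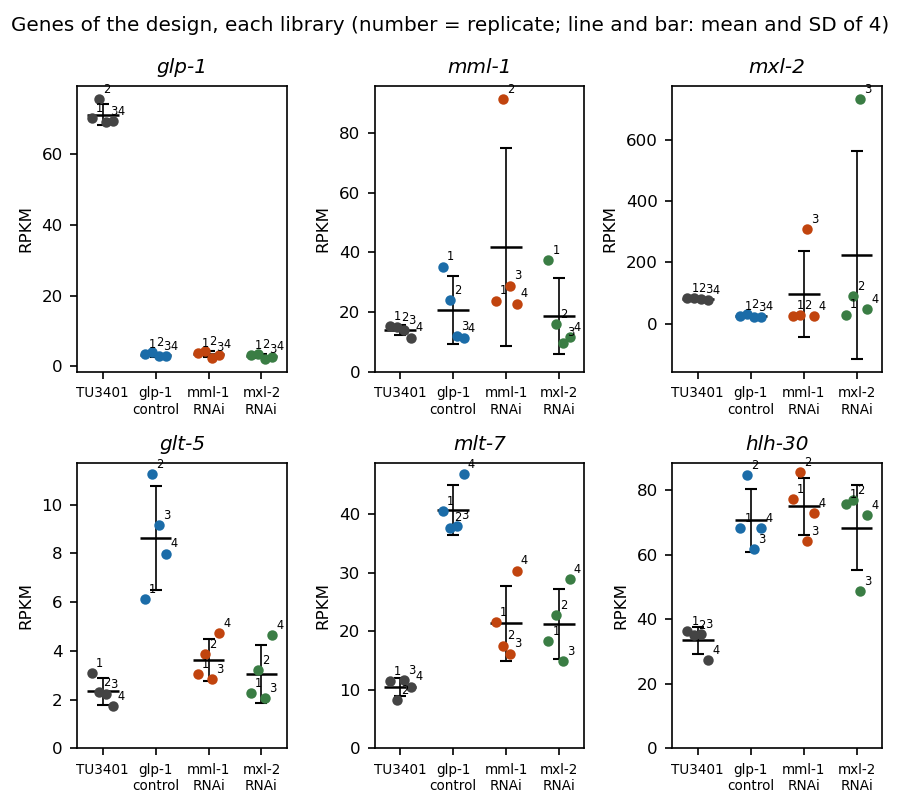
RPKM of 6 genes of the design in each library, by group; points are libraries with their replicate numbers, lines are group means and bars are SDs of 4 libraries. The mxl-2 panel shows 733 RPKM in mxl-2 RNAi replicate 3 and 308 RPKM in mml-1 RNAi replicate 3, and glt-5 and mlt-7 lie higher in the glp-1 control than in TU3401.

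The first comparison asks how germline-less animals differ from animals with a germline on the same RNAi. Transcripts of the germline, of oocytes and of cell division were nearly gone in glp-1, while transcripts of neurons, neuropeptides, muscle, lysosomes, immune defence and detoxification were a higher share of the reads. Of the 18 lists that camera called here, 3 stayed called with an estimated correlation and 0 with that and the block (lowest adjusted p = 0.112). The receptor gene glp-1 itself (chromosome III, 9092241 to 9099698) fell from 71.1 ± 3.02 to 3.29 ± 0.55 RPKM (SD, n = 4), a log2 fold change of -4.08 (SE 0.10, limma adjusted p = 5.61e-10, lower in 4 of 4 pairs). The small heat shock gene sip-1 fell from 3288 ± 570 to 0.311 ± 0.121 RPKM and the eggshell gene cpg-1 from 1239 ± 77.1 to 0.164 ± 0.0625 RPKM. Of 13563 genes tested, 5626 were higher and 6253 lower in glp-1 at limma adjusted p under 0.05 (5729 and 6275 with the replicate block), and 3837 and 5090 of these changed at least 2-fold. The libraries of the 2 groups did not overlap for 11317 genes (83.4%), where chance gives 2.86%. RPKM values are shares of a library, and the loss of germline RNA raises the share of all other RNA. Quantile scaling moved the median log2 fold change of all genes from -0.06 to 0.42 and the calls to 6730 higher and 5488 lower. Median-ratio scaling moved the median to 0.11.

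All 26 measured meiosis genes fell (median log2 fold change -4.78, camera adjusted p = 6.06e-09, 0.0769 with an estimated correlation), as did all 32 genes of DNA replication and cell cycle (median -6.38, camera adjusted p = 3.58e-11, 0.0165 with an estimated correlation, and 0.112 with that and the block). Of the 34 oocyte and germline genes 32 fell (median -7.63, camera adjusted p = 1.39e-09), and the list's adjusted p was 0.0927 with an estimated correlation. The 2 that rose were perm-2 and perm-4, which code for layers of the eggshell. The RNA-binding protein gene spn-4 went from 770.1 ± 30.99 RPKM to 3 reads in all 4 glp-1 control libraries together, and cey-2 from 2264 ± 179 to 0.833 ± 0.380 RPKM. The synaptonemal axis gene him-3 fell from 97.8 ± 2.001 to 0.0613 ± 0.0647 RPKM. Among replication and division genes, the helicase subunit gene mcm-2 fell from 198 ± 7.03 to 0.0318 ± 0.0263 RPKM and the kinase gene plk-1 from 215 ± 5.74 to 0.0605 ± 0.0460 RPKM (SD, n = 4 each). All 12 early embryo zygotic genes fell (median -3.21, camera adjusted p = 0.000865, 0.131 with an estimated correlation). Of 5 sperm genes 3 rose and 2 fell (camera adjusted p = 0.509), and of 9 somatic gonad genes 6 rose and 2 fell (camera adjusted p = 0.25). Ribosomal protein genes fell in 77 of 79 cases by a median log2 of -0.89 (camera adjusted p = 1.42e-06, 0.572 with an estimated correlation). The paralogs rpl-11.1 and rpl-11.2 went opposite ways, the first from 1872 ± 120 to 14.02 ± 1.13 RPKM and the second from 493 ± 19.6 to 1196 ± 72.5 RPKM.

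Of 29 neuron genes 25 rose (median log2 fold change 0.95, camera adjusted p = 3.07e-05, 0.234 with an estimated correlation), and the 2 that fell were tdc-1 and unc-119. The octopamine enzyme gene tbh-1 rose from 133 ± 8.73 to 971 ± 63.7 RPKM, a log2 fold change of 2.85 (SE 0.08, limma adjusted p = 9.69e-10, 4 of 4 pairs). That was well above the list's median, and whole-body RNA does not show in which tissue tbh-1 rose. Neuropeptide and insulin-like peptide genes rose in 86 of 101 cases and fell in 2 (median 1.41, camera adjusted p = 4.19e-11, 0.105 with an estimated correlation), among them nlp-20 from 25.7 ± 2.42 to 114 ± 5.48 RPKM. Of 27 muscle genes 24 rose (median 1.66, camera adjusted p = 3.23e-06, 0.131 with an estimated correlation), including the myosin gene unc-54 at 660 ± 30.2 RPKM in glp-1 and a log2 fold change of 2.13. Intestine genes rose in 16 of 25 cases (median 0.92, camera adjusted p = 0.00619, 0.322 with an estimated correlation), such as the esterase gene ges-1 from 16.05 ± 2.32 to 128 ± 13.7 RPKM. The list also holds clec-87, which fell from 2662 ± 106 to 0.615 ± 0.214 RPKM. Collagens and other hypodermis genes went both ways, 43 higher and 39 lower of 98 (median -0.01, camera adjusted p = 0.427). Fry called that list lower (fry adjusted p = 0.00103), but not with the block (0.191). All 6 vitellogenin genes rose (median 1.04, camera adjusted p = 0.0243, 0.441 with an estimated correlation), with vit-2 going from 5423 ± 720 to 11048 ± 1004 RPKM. Under quantile scaling vit-2 had a log2 fold change of -0.155 (limma adjusted p = 0.299), 3 of the 6 vitellogenins were called higher, and the list was no longer called (camera adjusted p = 0.622).

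Lysosome genes rose in 49 of 62 cases and fell in 5 (median 1.14, camera adjusted p = 2.81e-06, 0.131 with an estimated correlation). The hexosaminidase gene hex-1 rose from 37.4 ± 1.42 to 285 ± 27.7 RPKM. Among autophagy genes 22 of 34 were lower and 6 higher (median -0.68, camera adjusted p = 0.0923). Under quantile scaling 15 were higher and 13 lower. The ubiquitin-like autophagosome gene lgg-1 rose from 1168 ± 83.5 to 1851 ± 309 RPKM (log2 fold change 0.65, SE 0.12, limma adjusted p = 0.000573). The transcription factor gene hlh-30, the worm relative of TFEB, rose from 33.4 ± 4.16 to 70.6 ± 9.78 RPKM (log2 fold change 1.06, limma adjusted p = 2.92e-05). The P-granule autophagy receptor gene sepa-1 went from 24.2 ± 2.33 RPKM (955 to 1338 reads per library) to no read in any glp-1 control library, at least 1625-fold lower against a floor of 3 reads over the group, and epg-2 from 85.2 ± 6.86 to 4.34 ± 0.763 RPKM. Of 9 heme peroxidase genes 7 rose and 1 fell (median 1.34, camera adjusted p = 0.0213, 0.131 with an estimated correlation). The peroxidase gene mlt-7 (chromosome II, 4393007 to 4404850) rose from 10.5 ± 1.58 to 40.8 ± 4.26 RPKM, a log2 fold change of 1.87 (SE 0.12, limma adjusted p = 3.98e-07, 4 of 4 pairs), and skpo-3 from 10.1 ± 0.434 to 47.3 ± 4.63 RPKM. Genes of peroxide removal and thiol redox split evenly, 16 higher and 16 lower of 34 (camera adjusted p = 0.427). Under quantile scaling 18 of them were higher and 10 lower, and under median-ratio scaling 17 and 12.

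Genes of glutamate transport and metabolism rose in 15 of 20 cases and fell in 3 (median log2 fold change 1.22, camera adjusted p = 0.00745, 0.131 with an estimated correlation). Fry gave that list the sign down (fry adjusted p = 0.00588), and its 3 lowered members were gln-5, gln-6 and glna-3. The glutamate transporter gene glt-5 (chromosome II, 9706481 to 9708885) rose from 2.34 ± 0.563 to 8.63 ± 2.14 RPKM, a log2 fold change of 1.52 (SE 0.19, limma adjusted p = 4.22e-05, 4 of 4 pairs). The glutaminase gene glna-2 rose from 8.37 ± 1.18 to 38.6 ± 3.06 RPKM. Of 11 glutamate receptor genes 9 rose (median 0.78, camera adjusted p = 0.0120, 0.394 with an estimated correlation), with the chloride channel gene avr-15 at 5.55 ± 0.160 and 24.01 ± 2.003 RPKM. Fatty acid metabolism genes rose in 35 of 53 cases and fell in 8 (median 1.15, camera adjusted p = 0.000357, 0.241 with an estimated correlation), as in maoc-1 from 41.7 ± 4.25 to 181 ± 14.6 RPKM. Of 51 innate immunity genes 40 rose (median 1.58, camera adjusted p = 1.40e-06, 0.0165 with an estimated correlation, and 0.112 with that and the block), and the lysozyme gene lys-7 went from 997 ± 177 to 5956 ± 318 RPKM and lys-8 from 406 ± 33.2 to 1594 ± 63.3 RPKM. Xenobiotic detoxification genes, the cytochrome P450s and the glutathione and glucuronosyl transferases, rose in 109 of 134 cases and fell in 4 (median 1.43, camera adjusted p = 1.09e-10, 0.00717 with an estimated correlation, and 0.112 with that and the block). Among them, cyp-37A1 rose from 11.8 ± 2.09 to 81.1 ± 4.096 RPKM and gst-4 from 37.5 ± 5.26 to 248 ± 31.9 RPKM.

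DAF-16 targets rose in 21 of 23 cases (median log2 fold change 2.28, camera adjusted p = 8.18e-05, 0.131 with an estimated correlation), such as the trehalose synthase gene tps-1 from 9.44 ± 0.934 to 49.6 ± 4.79 RPKM. The 2 that fell were lea-1 and sip-1. The gene daf-16 itself stood at 56.1 ± 2.80 and 64.2 ± 11.7 RPKM, a log2 fold change of 0.17 (limma adjusted p = 0.218, but 0.000112 with quantile and 0.0493 with median-ratio scaling). Without glp-1 control replicate 4 its log2 fold change was 0.292 (limma adjusted p = 0.0160). Without glp-1 control replicate 1 it was 0.078 (limma adjusted p = 0.510). Germline longevity regulators split, 9 higher and 10 lower of 24 (camera adjusted p = 0.747 with the sign up, and fry adjusted p = 0.00103 with the sign down). With quantile scaling 13 of these regulators were higher and 9 lower. Their lowered members included the heat shock factor gene hsf-1, from 67.9 ± 4.37 to 13.3 ± 1.56 RPKM. In the Myc and Mondo network 3 of 6 genes rose and 2 fell (camera adjusted p = 0.725 with the sign up, and fry adjusted p = 0.00165 with the sign down), with mxl-2 falling to 24.7 ± 4.003 RPKM (log2 fold change -1.69, limma adjusted p = 3.36e-07, but 0.0832 when all 4 groups shared 1 fit). Heat shock and unfolded protein response genes were higher in 8 and lower in 14 of 29 cases (camera adjusted p = 0.427). The largest rises among all genes included scl-20, from 0.183 ± 0.323 to 380.0 ± 279 RPKM, H39E23.3 from 0.112 ± 0.101 to 248 ± 113 RPKM, clx-1 from 1.36 ± 1.52 to 435 ± 260 RPKM and dhs-26 from 6.91 ± 12.63 to 419 ± 329 RPKM (SD, n = 4). Reads of sid-1, whose product is the double-stranded RNA channel, rose from 123 ± 17.3 to 189 ± 41.7 RPKM (limma adjusted p = 0.00780, 4 of 4 pairs). This background lacks the channel except in neurons, so these reads do not show how sid-1 behaves in worms without that background. For each of the 26 lists, counts of calls adjusted over the list alone were the same as over all genes tested, with and without the block. The block changed the counts of 9 lists. With it, 90 neuropeptide and insulin-like peptide genes, 17 intestine, 48 lysosome and 42 innate immunity genes were higher. Higher and lower were 46 and 40 for hypodermis and collagen, 9 and 11 for germline longevity regulator, 35 and 9 for fatty acid metabolism, 108 and 6 for xenobiotic detoxification, and 9 and 14 for heat shock and unfolded protein response.

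**Figure D2:**
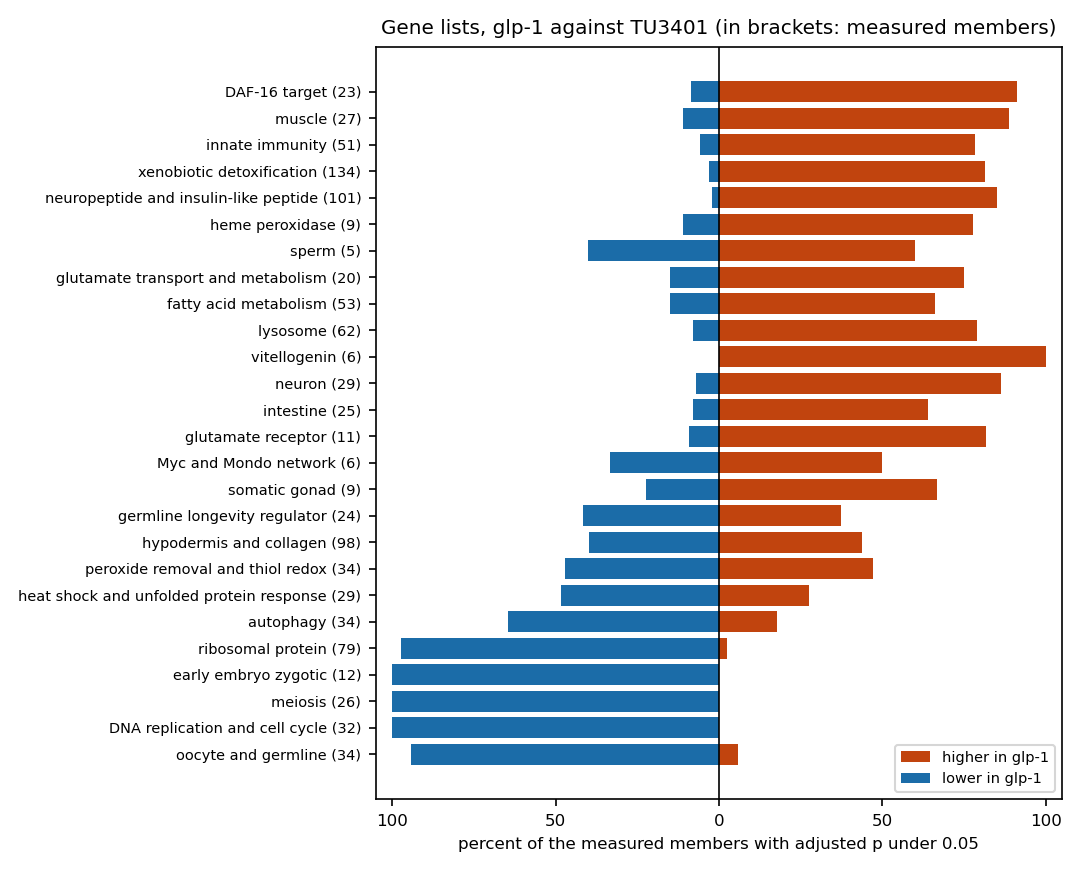
Gene lists in glp-1 against TU3401; bars give the percent of each list's measured members (number in brackets) with limma adjusted p under 0.05, higher in glp-1 to the right and lower to the left, ordered by median log2 fold change. Meiosis and DNA replication reach 100% lower, and vitellogenin reaches 100% higher with the values as deposited but not under quantile scaling.

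The second comparison asks what mml-1 RNAi, delivered to neurons, did to the transcripts of germline-less animals. Besides a piRNA locus, 1 gene passed the test. The gene slcf-2 (chromosome X, 3393862 to 3397657) fell from 9.91 ± 0.463 to 2.098 ± 0.597 RPKM (SD, n = 4), a log2 fold change of -1.83 (SE 0.14, limma adjusted p = 0.00789, lower in 4 of 4 pairs). The piRNA locus 21ur-6565 was also called lower (limma adjusted p = 0.0251) but held only 1 or 2 reads per control library and none in the libraries labelled mml-1 RNAi. In all, 0 genes were higher and 2 lower of 12591 tested by limma, with 985 at unadjusted p under 0.05, where chance gives 630. With the replicate block 14 were higher and 46 lower, with voom and the block 155 and 313, and the authors' deposited table has 75 of these genes under a false discovery rate of 0.05. The block shared 20 genes with the authors' 75. The number of calls changed when 1 library was left out. There were 53 calls without mml-1 RNAi replicate 4, 5 without control replicate 2, and 1 without mml-1 RNAi replicate 1 or 2. Without control replicate 1, 3 or 4 or mml-1 RNAi replicate 3 limma made 0 calls, and slcf-2 then stood at limma adjusted p = 0.0684 to 0.0763. Its log2 fold change lay between -1.96 and -1.76 in all 8 of these fits.

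Further genes were called lower or higher in the libraries labelled mml-1 RNAi with the replicate block, as follows. The block called 60 genes, and leaving out control replicates 1 to 4 in turn changed that to 1, 0, 0 and 246, and leaving out mml-1 RNAi replicates 1 to 4 to 1, 0, 0 and 245. With the block, a library whose partner is left out adds nothing to the difference. Both series therefore leave out the same pairs and are not separate checks. The glucuronosyl transferase gene ugt-41 stood at 316 ± 66.6 and 85.1 ± 24.4 RPKM (log2 fold change -1.91, limma adjusted p = 0.108, 0.0288 with the block, lower in 4 of 4 pairs) and ugt-27 at 12.5 ± 2.58 and 5.13 ± 1.29 RPKM (0.169, and 0.0288 with the block). Collagen col-36 stood at 10.5 ± 5.66 and 2.13 ± 1.95 RPKM (limma adjusted p = 0.367, 0.0278 with the block). The gut esterase ges-1 (log2 fold change -0.50) and the lipase lipl-2 (-0.66) were lower, and hsp-43 (0.68) was higher, at limma adjusted p = 0.0466, 0.0383 and 0.0424 with the block and 0.375, 0.470 and 0.410 without it. Other genes, chosen after their values were seen, were dpyd-1, which codes for a pyrimidine-degrading enzyme, at 31.7 ± 2.83 and 56.8 ± 3.38 RPKM (limma adjusted p = 0.0511, 0.0288 with the block), F23F12.12 at 587 ± 130 and 102 ± 42.5 RPKM (0.0511 and 0.0397), and F41C3.1 at 3.65 ± 0.926 and 24.8 ± 10.4 RPKM (0.108 and 0.0317). Also chosen after their values were seen, C53A3.2 (log2 fold change -1.65), C07B5.8 (-1.998), T22B7.3 (-1.78) and col-183 (-1.58) were lower at limma adjusted p = 0.0383, 0.0288, 0.0332 and 0.0288 with the block, and were not called without it.

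Genes of the design differed as follows in the libraries labelled mml-1 RNAi. The transporter glt-5 stood at 3.62 ± 0.850 RPKM against 8.63 ± 2.14 in the control (log2 fold change -1.05, SE 0.19, limma adjusted p = 0.173, 0.0587 with the block and 0.00929 with voom and the block). In the authors' deposited table its false discovery rate was 0.000486, and over all alternatives its adjusted p lay between that and 0.558. The peroxidase gene mlt-7 stood at 21.4 ± 6.39 against 40.8 ± 4.26 RPKM (-0.94, SE 0.19, limma adjusted p = 0.194, 0.0383 with the block, and 0.0285 without the block when mml-1 RNAi replicate 4 was left out). The autophagy genes lgg-1 (2032 ± 393 RPKM, log2 fold change 0.13) and hlh-30 (74.9 ± 8.89 RPKM, 0.09), and daf-16 (62.7 ± 8.84 RPKM, -0.02), glp-1 (0.04) and sid-1 (0.08) had limma adjusted p from 0.955 to 0.994. The acyl-CoA synthetase gene acs-2 was above the control in all 4 pairs but with a wide spread, at 13.3 ± 11.5 and 499 ± 337 RPKM (log2 fold change 4.86, SE 1.05, limma adjusted p = 0.227, 0.0848 with the block, 0.0285 without mml-1 RNAi replicate 4). The acyl-CoA dehydrogenase gene acdh-1 stood at 32.4 ± 24.9 and 178 ± 118.9 RPKM (2.52, limma adjusted p = 0.354). In the authors' deposited table acs-2 had a false discovery rate of 1.13e-07 and acdh-1 of 0.00552.

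Of the 25 lists tested in that comparison 3 were called, each by a small shift of its members. Muscle genes were above 0 in 25 of 27 cases (median log2 fold change 0.11, camera adjusted p = 0.00386, 0.938 with an estimated correlation), with unc-60 at 0.23 and lev-11 at 0.18. Ribosomal protein genes were above 0 in 73 of 79 cases (median 0.06, camera adjusted p = 0.00386, 0.938 with an estimated correlation), as in rps-25 at 0.16. All 7 somatic gonad genes were below 0 (median -0.09, camera adjusted p = 0.0124, 0.896 with an estimated correlation, 0.0740 with the block), and the gap junction genes inx-9 (-0.39) and inx-8 (-0.31) passed when adjusted over the list alone. With the block, heat shock and unfolded protein response genes were called lower (21 of 29 below 0, median -0.11, camera adjusted p = 0.0368, 0.104 without it), among them pdi-2 at -0.48. With an estimated correlation that list's adjusted p was 0.864 with the block and 0.896 without it. No member of any list was called by limma over all genes without the block. Adjusted over the list alone, heme peroxidase had 0 higher and 3 lower, glutamate transport and metabolism 1 and 1, and xenobiotic detoxification 1 and 5. With the block the counts over the list alone were 4 and 10 for fatty acid metabolism, 8 and 8 for hypodermis and collagen, 5 and 7 for xenobiotic detoxification, 5 and 5 for innate immunity, 1 and 6 for heat shock and unfolded protein response, 4 and 3 for neuropeptide and insulin-like peptide, 3 and 2 for glutamate transport and metabolism, and 1 and 2 for lysosome. None was higher and 3 were lower for heme peroxidase and for germline longevity regulator, 2 for intestine, and 1 for autophagy and for somatic gonad. The camera adjusted p of the other lists were 0.0915 for heme peroxidase, 0.104 for DNA replication and cell cycle, 0.114 for neuron, 0.121 for glutamate receptor, 0.199 for oocyte and germline and for neuropeptide and insulin-like peptide, 0.251 for the Myc and Mondo network, 0.418 for innate immunity, 0.47 for vitellogenin and 0.601 for glutamate transport and metabolism. They were 0.685 for DAF-16 target, lysosome, peroxide removal and xenobiotic detoxification, 0.868 for germline longevity regulator, 0.89 for sperm, 0.935 for autophagy, and 0.972 for meiosis, intestine, hypodermis and collagen, and fatty acid metabolism. Early embryo zygotic genes had 1 measured member and were not tested.

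The third comparison asks the same of mxl-2 RNAi. It gave 13 calls, 2 higher and 11 lower. The gene slcf-2 fell from 9.91 ± 0.463 to 2.06 ± 0.339 RPKM (SD, n = 4), a log2 fold change of -1.84 (SE 0.12, limma adjusted p = 0.00120, lower in 4 of 4 pairs), and it was called in all 8 fits that left out 1 library. The gene gfat-1, for the first enzyme of hexosamine synthesis, fell from 188 ± 26.7 to 47.4 ± 20.6 RPKM (limma adjusted p = 0.0409, 0.0548 with the block). F23F12.12 fell from 587 ± 130 to 88.9 ± 34.7 RPKM (0.0224), F36H12.3 from 6.35 ± 2.64 to 0.161 ± 0.289 RPKM (0.0372), C53A3.2 from 127 ± 30.2 to 36.4 ± 7.37 RPKM (0.0224, 0.0548 with the block), ugt-41 from 316 ± 66.6 to 102 ± 20.6 RPKM (0.0332) and ugt-25 from 74.95 ± 11.7 to 24.8 ± 7.10 RPKM (0.0371, 0.0548 with the block), all lower in 4 of 4 pairs. For genes picked as largest falls, the rule of no overlap fixes that count of pairs. The genes F41C3.1, from 3.65 ± 0.926 to 27.3 ± 9.52 RPKM (limma adjusted p = 0.0332), and dpyd-1, from 31.7 ± 2.83 to 57.0 ± 6.85 RPKM (0.0497), rose. Outside the rule for named genes, and chosen after their values were seen, F44E7.2 fell from 127 ± 10.6 to 58.8 ± 8.43 RPKM (limma adjusted p = 0.0224) and the G protein gene gpa-10 from 3.57 ± 0.909 to 0.972 ± 0.127 RPKM (0.0497, 0.0601 with the block). The piRNA loci 21ur-6778 (0.0452, 0.0548 with the block) and 21ur-13915 (0.0122) held 1 to 3 reads per control library and none in the libraries labelled mxl-2 RNAi.

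In all, 2 genes were higher and 11 lower of 12581 tested by limma, with 823 at unadjusted p under 0.05, where chance gives 629. With the replicate block 8 were higher and 16 lower, with voom and the block 117 and 151, and the authors' deposited table has 63 of these genes under a false discovery rate of 0.05. Leaving out control replicates 1 to 4 in turn changed the 24 calls with the block to 23, 7, 0 and 86, and leaving out mxl-2 RNAi replicates 1 to 4 to 26, 7, 0 and 87. Both series leave out the same pairs and are not separate checks. Without the block, leaving out 1 library gave 1 call without control replicate 2, 3 or 4 or mxl-2 RNAi replicate 2 or 3, 4 without control replicate 1, 9 without mxl-2 RNAi replicate 1 and 16 without mxl-2 RNAi replicate 4. With the block, cyp-34A8 was also higher (65.3 ± 4.68 and 99.5 ± 5.57 RPKM, limma adjusted p = 0.0739, 0.0413 with the block). The transporter glt-5 stood at 3.04 ± 1.18 RPKM (log2 fold change -1.27, SE 0.23, limma adjusted p = 0.146, 0.0665 with the block) and mlt-7 at 21.2 ± 6.03 RPKM (-0.95, SE 0.19, 0.180, 0.0548 with the block). Both were lower in 4 of 4 pairs. In the authors' deposited table their false discovery rates were 4.65e-05 and 0.00599, and over all alternatives their adjusted p reached 0.462 and 0.472. The genes lgg-1 (1820 ± 325 RPKM), hlh-30 (68.3 ± 13.2 RPKM), daf-16 (67.1 ± 5.12 RPKM), glp-1 (2.86 ± 0.593 RPKM) and sid-1 (212 ± 47.8 RPKM) had limma adjusted p from 0.928 to 0.987. The gene acs-2 stood at 356 ± 293 RPKM (log2 fold change 4.31, SE 1.04, limma adjusted p = 0.329, 0.127 with the block) and acdh-1 at 266 ± 92.7 RPKM (3.27, SE 0.54, 0.132, 0.0665 with the block), both higher in 4 of 4 pairs. In the authors' deposited table their false discovery rates were 3.15e-06 and 9.62e-07.

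Of the 25 lists tested with mxl-2 RNAi 5 were called. Ribosomal protein genes were above 0 in 77 of 79 cases (median log2 fold change 0.08, camera adjusted p = 0.00332, 0.926 with an estimated correlation), for example rps-21 at 0.13. Heat shock and unfolded protein response genes were below 0 in 24 of 29 cases (median -0.17, camera adjusted p = 0.0219, 0.305 with an estimated correlation, fry adjusted p = 0.00522), with the disulfide isomerase gene pdi-2 at -0.45, while hsp-43 stood at 0.47. The calls of the other 3 lists ended with the block. Over all genes tested no member of these 3 was called. They were peroxide removal and thiol redox, above 0 in 20 of 33 cases (median 0.09, camera adjusted p = 0.0331, 0.867 with an estimated correlation, 0.0546 with the block), neuron, below 0 in 23 of 30 (median -0.12, 0.0331, 0.911 with an estimated correlation, 0.0546 with the block), and somatic gonad, below 0 in 7 of 7 (median -0.12, 0.0331, 0.863 with an estimated correlation, 0.0603 with the block). Examples were gsr-1 at 0.30, sod-1 at 0.31, unc-17 at -0.40 and inx-9 at -0.20. The other 20 lists had camera adjusted p from 0.0606 to 0.857. Of 146 xenobiotic detoxification genes 2 fell over all genes tested, and adjusted over the list alone 2 were higher and 6 lower (camera adjusted p = 0.223). With the block these counts were 2 higher and 2 lower over all genes, and 14 higher and 11 lower over the list alone. Adjusted over the list alone, fatty acid metabolism had 2 higher and 1 lower, DAF-16 target 1 and 0, glutamate transport and metabolism 1 and 1, and heme peroxidase 0 and 1. With the block they became 7 and 3, 2 and 1, 2 and 2, and 0 and 1. In other lists the block gave 9 and 9 for hypodermis and collagen, 3 and 7 for innate immunity, 1 and 7 for heat shock and unfolded protein response, 1 and 1 for neuropeptide and insulin-like peptide, 2 and 0 for peroxide removal and thiol redox, 0 and 2 for glutamate receptor and for the Myc and Mondo network, and 0 and 1 for intestine. Several further members lay away from 0 without being called over all genes tested, among them gdh-1 (0.51), nlp-27 (0.48), col-140 (0.40) and lys-7 (-0.64).

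**Figure D3:**
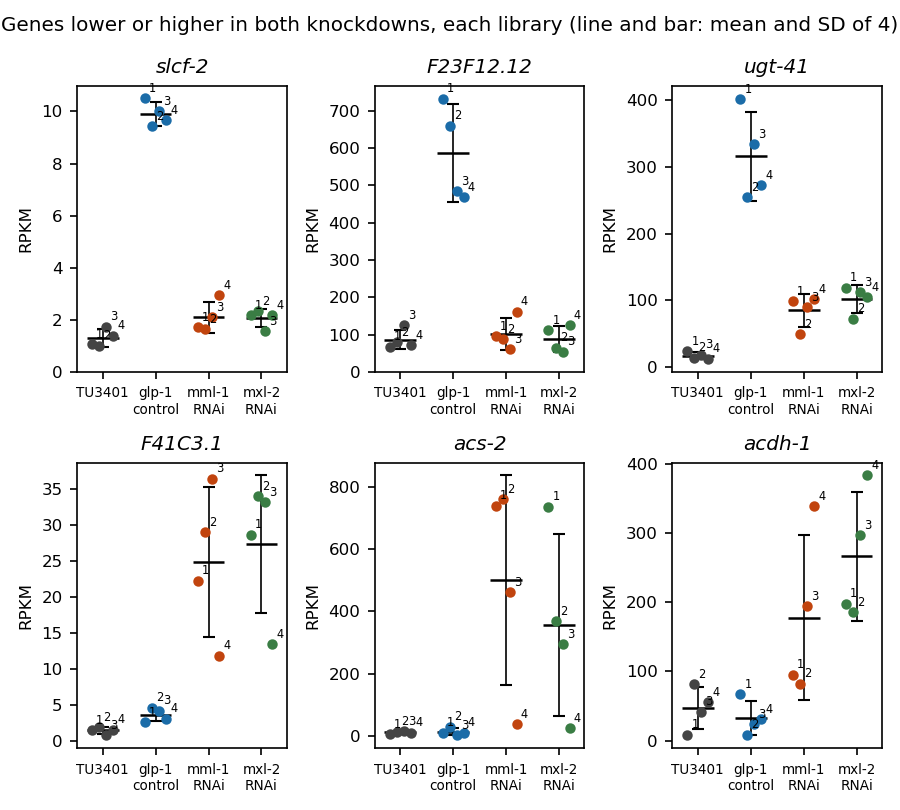
RPKM of 6 genes in each library, by group; points are libraries with replicate numbers, lines are means and bars are SDs of 4 libraries. The 4 libraries of each knockdown lie below the control for slcf-2, F23F12.12 and ugt-41 and above it for F41C3.1, while acs-2 and acdh-1 vary widely between numbers.

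The knockdowns were also compared with each other. Limma called 0 of 12540 genes between the libraries labelled mxl-2 RNAi and mml-1 RNAi, with 111 at unadjusted p under 0.05 where chance gives 627. That fit leaves the differences between replicate numbers in its error, which makes it cautious for paired libraries. Its 0 calls are therefore no sign that the knockdowns act alike. The replicate block gave 0 as well (872 unadjusted), and voom with the block called 2, chil-28 (log2 fold change -1.72) and ptr-22 (-1.74), both at adjusted p = 0.0287 and chosen after their values were seen. Of the 24 lists tested 3 were called, by small shifts. No member of these 3 was called, over all genes or over the list alone, with or without the block. In other lists the block called over the list alone 0 higher and 1 lower for DAF-16 target and 1 and 1 for the Myc and Mondo network. The difference, mxl-2 RNAi minus mml-1 RNAi, was below 0 for muscle genes in 25 of 27 cases (median -0.08, camera adjusted p = 2.79e-05), for autophagy genes in 26 of 33 (median -0.08, 0.00777), and above 0 for peroxide removal and thiol redox genes in 27 of 33 (median 0.10, 0.0214). With an estimated correlation all 3 had an adjusted p of 0.981. With the block, hypodermis and collagen (camera adjusted p = 0.0199) and fatty acid metabolism (0.0303) were called higher in addition, with adjusted p = 0.862 and 0.700 with an estimated correlation and the block.

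Changes common to both knockdowns were counted next. Over 12432 genes tested in both, slcf-2 was the 1 gene called lower in both, and none was called higher in both. With the replicate block 9 were lower and 3 higher in both. Both lists share the control libraries, so these counts are no measure of a common response. The 9 were slcf-2, ugt-41, col-36, F23F12.12, F36H12.3, C07B5.8, C14F11.6, T22B7.3 and ZK355.8, and the 3 were dpyd-1, F41C3.1 and F49F1.5, all as the block called them. The log2 fold changes of the 2 knockdowns correlated over genes at r = 0.793 with a covariance of 0.0671, and 78.2% had the same sign. Unchanged groups simulated against the same controls gave r = 0.508 (0.473 to 0.550), a covariance of 0.0339 and 66.8% of the same sign, so the difference in covariance was 0.0332. The simulated libraries carried each gene's full spread within groups, without pairing by number, and genes were drawn independently. The values for unchanged paired groups are therefore not known. Covariances computed from the single libraries of each replicate number had an SD of 0.0272 over the numbers. That SD is no spread of the covariance above, which rests on group means. With the controls split between the knockdowns r was 0.0464 to 0.449, but there the differences between numbers no longer cancel, and the value for unchanged groups is not known. In matched smaller sets that share no library r was 0.379 to 0.506.

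**Figure D4:**
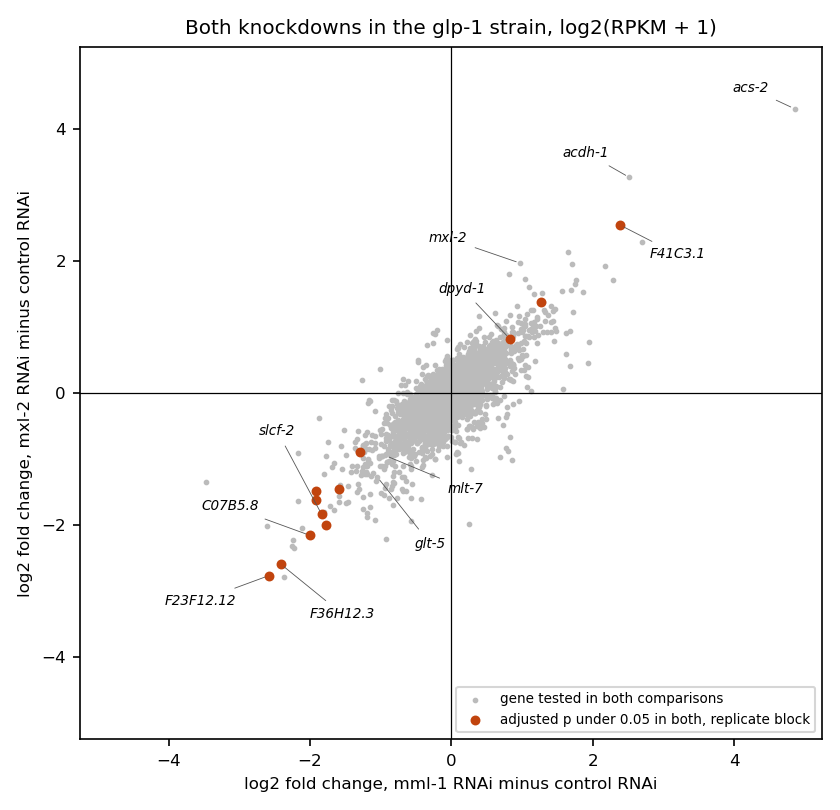
Log2 fold changes of mml-1 RNAi (x axis) and mxl-2 RNAi (y axis) against the shared control, on the log2(RPKM + 1) scale; each gray point is a gene tested in both, and the 12 red points have limma adjusted p under 0.05 in both with the replicate block. The genes acs-2 and acdh-1 lie far up in both without being called.

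The last comparison asks whether the knockdowns moved genes back toward the TU3401 level. Among the genes called in glp-1 against TU3401, mml-1 RNAi moved 63.3% of 10446 the opposite way and mxl-2 RNAi 62.5% of 10448. Simulated unchanged groups that share the control gave 51.8% (50.4 to 52.8) and 51.9% (50.8 to 53.04). These ranges come from independently drawn genes without pairing by number. They do not show how far unchanged paired groups would spread. Single replicate numbers gave 55.5 to 61.2% for mml-1 RNAi and 55.1 to 60.9% for mxl-2 RNAi. The covariances with the glp-1 difference were -0.140 and -0.134, against -0.0332 and -0.0329 in the simulations, a difference of -0.107 and -0.101. With the controls split, so that no library entered both differences, the shares were 54.2 to 60.7% for mml-1 RNAi and 55.8 to 60.4% for mxl-2 RNAi, with covariances from -0.127 to -0.0401 and from -0.114 to -0.0532. The lowest shares in these splits were 49.7 and 46.1% for genes higher in glp-1, and 47.1 and 49.5% for lower genes. In these splits the differences between numbers do not cancel, and the shares for unchanged groups are not known. Levels of single genes were, for slcf-2, 1.30 ± 0.335 RPKM in TU3401 and 9.91 ± 0.463 in the glp-1 control, and for F23F12.12 86.4 ± 26.3 and 587 ± 130 RPKM. For ugt-41 the levels were 17.3 ± 4.97 RPKM in TU3401 and 316 ± 66.6 in the control (SD, n = 4), so both knockdown groups remained above TU3401. The genes dpyd-1 and F41C3.1 went further from the TU3401 levels of 22.2 ± 3.08 and 1.47 ± 0.493 RPKM. So did gfat-1, which stood at 259 ± 30.4 RPKM in TU3401 and 188 ± 26.7 in the control. Its levels were 46.4 ± 24.3 RPKM under mml-1 RNAi and 47.4 ± 20.6 RPKM under mxl-2 RNAi.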

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

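The weighing tests of this part other than the test of mixed RNA, the first test of germline tissue and the splits of the libraries were chosen only after the result was seen. Of 197 groups of 4 libraries examined for a library far from the other 3, 17 (8.63%) held one, where chance gives about 1 in 20.

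Far from the other 3 libraries of their group were the following RPKM values. Among the TU3401 libraries, replicate 2 had 75.6 for glp-1 (others 69.2 to 70.3), replicate 3 had 149 for sid-1 (111.6 to 117), and replicate 4 had 27.2 for hlh-30 (35.003 to 36.2). TU3401 replicate 1 had 0.665 for scl-20 (0 to 0.0671), 0.261 for H39E23.3 (0.0395 to 0.0765), 25.9 for dhs-26 (0.533 to 0.642) and 45.4 for gst-4 (34.4 to 35.4). In the glp-1 control, replicate 2 had 15.6 for hsf-1 (12.26 to 12.64) and 6.09 for unc-17 (3.54 to 3.88), and replicate 4 had 3.498 for 21ur-6565 (2.01 to 2.24) and 5.25 for 21ur-6778 (2.01 to 2.24), which are 1 to 3 reads. The library labelled mml-1 RNAi replicate 2 had 1935 for nlp-27 (1641 to 1651) and 91.5 for mml-1 (22.9 to 28.9). Replicate 3 of that group had 308 for mxl-2 (25.4 to 26.98). Of the libraries labelled mxl-2 RNAi, replicate 3 had 733 for mxl-2 (29.3 to 90.7) and 48.8 for hlh-30 (72.1 to 76.9), and replicate 4 had 0.594 for F36H12.3 (0 to 0.0516).

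Between the knockdowns, camera found a difference in 3 lists. The median log2 difference, mxl-2 RNAi minus mml-1 RNAi, was -0.0775 for muscle, -0.0808 for autophagy and 0.0962 for peroxide removal and thiol redox. With an estimated correlation all 3 had an adjusted p of 0.981. Of the 35 splits of these 8 libraries, 22 gave at least as many lists, the highest other giving 11 against the real 3. The numbers pair the libraries, and the 8 splits that part all pairs are too few for a share under 0.05.

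The first pattern is the reads of the knockdown targets, which were not lower than in the control and were far higher in a few libraries. In whole-body RNA a fall confined to neurons could go unseen. An exchange of labels between the number 3 RNAi libraries is argued against, since the library labelled mxl-2 RNAi replicate 3 held 733 RPKM of mxl-2, above every library labelled mml-1 RNAi. The test of mixing of RNA between these libraries gave an SD over genes of their log2 difference of 0.353. That was not below the lowest of the other numbers (0.383, 0.457 and 0.302). This test cannot exclude mixing, because the other numbers differ widely and the SD of number 3 without mixing is not known. Reads from the RNAi food, whose bacteria carry a copy of the target's sequence, may account for the rises and remain open: mxl-2 stood 9.13-fold above the control mean (2.26-fold without mxl-2 RNAi replicate 3), 7 of 8 libraries lay above the same-numbered control for their own target, and 5 of 8 did so for the other target. The deposited values give no position or strand of the reads, so the level of the animals' own mml-1 and mxl-2 transcripts cannot be told apart from such reads, and no biological explanation was tested.

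The second pattern is the movement of genes toward the TU3401 level in both knockdowns. The sharing of control libraries between the differences is argued against as the whole cause. In the 12 matched smaller sets, where no library entered both differences, the covariance was below 0 each time and nearest to 0 at -0.0826. These sets reuse the same libraries, so they are not 12 independent checks. The spread for unchanged paired groups is not known either, so chance is not excluded. For germline tissue in the knockdown libraries, the first test did not decide: germline genes recovered 0.00205% of the TU3401 level on average, but other lowered genes recovered 0.790% with libraries on both sides of 0. A second test, chosen after the result of the first, argues against it, since adding the highest germline share seen to the control gave a covariance of -0.00163, or 1.62% of the -0.101 to be explained. An effect of the knockdowns on the animals and a difference in culture between the fed strains both may contribute and were not tested.

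The third pattern is the higher level of acs-2 and acdh-1 in both knockdowns, which limma did not call. The gene acdh-1 belongs to the propionate shunt, which worms use when vitamin B12 is low, and the other 4 shunt genes (ech-6, alh-8, and hach-1 and hphd-1 under their sequence names) lay above the control by a mean log2 difference of 0.631 over the 8 pairs, with a mean above 0 in all 4 numbers of both knockdowns (0.202 to 0.904 and 0.397 to 1.117). None of these 4 was called in either knockdown (limma adjusted p = 0.576 to 0.939, and 0.0629 to 0.296 with the block). Genes of B12-dependent propionate breakdown had means of -0.0493 under mml-1 RNAi and -0.0334 under mxl-2 RNAi. A response to low B12 or to propionate is thus only a candidate explanation for acdh-1. Whether it came through the food or the knockdown is open, and it does not cover acs-2, which is no shunt gene. Food shortage cannot be told apart: 7 other genes induced by fasting had a mean of -0.125 but went both ways. Of these, icl-1 and cpt-3 lay above the control in 8 of 8 pairs and hacd-1 below it in 8 of 8. Both knockdowns are set against the same 4 control libraries. Neither these counts nor the shunt mean therefore rests on 8 independent pairs.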

How the results depend on the processing

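Limma's voom, the filter on gene length, the settings that join the block with another choice, and the matched smaller sets of libraries were chosen after seeing the data. With the block, leaving out either library of a pair leaves out the whole pair, so the counts of settings in this part hold such fits in duplicate. In glp-1 against TU3401 the called genes named here kept direction and call in 1246 of 1248 settings. The exceptions were mxl-2 with all 4 groups in 1 fit (limma adjusted p = 0.0832) and vit-2 under quantile scaling (-0.155). The called lists numbered 3 with an estimated correlation and 0 with that and the block. Fry gave the opposite sign to camera for hypodermis and collagen (median -0.00681), germline longevity regulator (0.0471), Myc and Mondo network (0.721) and glutamate transport and metabolism (1.22), and with the block still for germline longevity regulator (0.0471) and Myc and Mondo network (0.721). The cause was not tested for any change in this part unless stated.

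Under mml-1 RNAi limma called 2 genes as reported, 6 with a pseudocount of 0.1, and 1 with a pseudocount of 5, with a mean of at least 5 RPKM, or with genes of at least 200 bases, which leaves out the piRNA locus by construction. It called 60 with the block, 39 with all 4 groups in 1 fit and 388 with both, 148 with the block and a mean of at least 5 RPKM, and 217 with the block and genes of at least 200 bases. Voom with the block called 468, and the authors' deposited table has 75. Leaving out 1 library gave 0 to 53 without the block. With the block it gave 1, 0, 0 and 246 without control replicates 1 to 4 and 1, 0, 0 and 245 without mml-1 RNAi replicates 1 to 4. Of 3 lists called, 0 were called with an estimated correlation, 0 by fry, and 0 by either with the block. Leaving out 1 library gave 0 to 6 lists. The genes called kept their call in 32 settings and lost it in 26, all in the same direction. Those not called stayed so in 882, were called in 155 and moved in 15.

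Under mxl-2 RNAi limma called 13 genes as reported, 2 with all genes above 0 in at least 1 library, 8 with a mean of at least 5 RPKM, 24 with the block, 25 with all 4 groups in 1 fit and 166 with both. With the block it called 100 at a mean of at least 5 RPKM and 161 among genes of at least 200 bases. Voom with the block called 268, and the authors' deposited table has 63. Leaving out 1 library gave 1 to 16. With the block it gave 23, 7, 0 and 86 without control replicates 1 to 4 and 26, 7, 0 and 87 without mxl-2 RNAi replicates 1 to 4. The 5 lists called became 0 with an estimated correlation, 1 with fry, 2 with the block, 0 with the block and an estimated correlation, and 1 with the block and fry, and 1 to 5 without 1 library. The genes called kept their call in 212 settings and lost it in 182, all in the same direction.

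Between the knockdowns limma called 0 genes (111 unadjusted), also without any 1 library, and voom with the block called 2. The 3 lists became 0 with an estimated correlation, 0 with fry, 5 with the block, 0 with the block and an estimated correlation, 0 with the block and fry, and 2 to 7 without 1 library. The median of the ribosomal protein list, which was not called, turned from 0.0148 to -0.0260 without mml-1 RNAi replicate 2, -0.0449 without mxl-2 RNAi replicate 1 and -0.0129 without mxl-2 RNAi replicate 3, with a highest value of 0.0623 without mml-1 RNAi replicate 1.

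Genes called in both knockdowns numbered 1 as reported, 4 with a pseudocount of 0.1, 12 with the block, 0 with the controls split and 0 in the matched smaller sets, both of which have fewer libraries, and 0 to 10 without 1 library. The covariance of the knockdowns was 0.124 with a pseudocount of 0.1, and 0.0340, 0.00646, 0.0351 and 0.0398 in 4 of the 6 splits of the controls. The share of genes moving against the glp-1 difference was 54.2, 60.3, 59.2, 60.01, 60.01 and 60.7% in the splits for mml-1 RNAi and 56.4 and 59.9% in the matched sets that moved most. For mxl-2 RNAi it was 55.8, 58.0, 58.9 and 58.0% in splits and 57.9, 56.9 and 58.5% in matched sets. Without 1 library it was 60.8 to 64.03% and 59.4 to 63.2%. Depth limits statements on genes with few reads: 1 read of a 1 kb gene was 0.0367 to 0.0531 RPKM.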

Other observations

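The gene families of the next 2 paragraphs, and their camera tests, were chosen only after the data were seen, while the counts of other splits were planned. In glp-1 against TU3401, families outside the lists also moved together. Nuclear hormone receptor genes (nhr) were higher in 131 of 168 cases and lower in 17 (camera adjusted p = 1.17e-07, 0.268 with an estimated correlation). Transthyretin-related genes (ttr) were higher in 42 of 49 (camera adjusted p = 2.31e-07), C-type lectins (clec) in 63 of 85 with 9 lower (1.62e-05), potassium channels of the twk family in 22 of 26 with 0 lower (4.80e-05), neuropeptide receptors (npr) in 18 of 20 with 0 lower (0.000585) and bestrophin chloride channels (best) in 16 of 19 with 0 lower (0.000366). None of these 5 was called with an estimated correlation, where the adjusted p was 0.308 for best and 0.268 for the others.

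Families lower in glp-1 included nuclear pore genes (npp), 22 of 22 (camera adjusted p = 8.39e-07), F-box genes of the fbxb family, 70 of 70 (4.19e-10), mitochondrial ribosome genes, 39 of 39 in mrpl and 27 of 27 in mrps (8.39e-07 and 2.60e-05), Mediator subunits (mdt), 18 of 19 (0.000259), and transcription factor subunits of the taf family, 17 of 17 (6.93e-05). None of these 6 was called with an estimated correlation, where the adjusted p was 0.370 for mrpl and mrps, 0.322 for mdt and 0.268 for the others. The related fbxa family went the other way, 69 of 108 higher and 23 lower (camera adjusted p = 0.00795, 0.490 with an estimated correlation). Of 51 families 31 were called, and 0 with an estimated correlation, where the lowest camera adjusted p was 0.268. These directions held under quantile and median-ratio scaling. Vitellogenin transcripts took 7.22 ± 0.742% of the reads in TU3401, 15.9 ± 1.73% in the glp-1 control, 17.3 ± 1.64% under mml-1 RNAi and 16.38 ± 1.55% under mxl-2 RNAi (SD, n = 4).

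The counts were compared with those of the 35 splits of each comparison's 8 libraries into groups of 4. For glp-1 against TU3401, 1 split, the real one, gave as many as 11879 genes, the highest other giving 1, while 8 gave at least 18 lists (highest other 19). The other 7 each keep 3 of the 4 libraries of a group together and so carry part of the real difference, and the splits that take 2 libraries of each group gave 0 to 6 lists. For the number of lists the splits therefore decide nothing. For mml-1 RNAi, 6 splits gave at least the 2 genes and 33 at least the 3 lists (highest others 413 and 12). The split that gave 413 set numbers 1 and 2 against 3 and 4, which points to a structure of the samples by number. For mxl-2 RNAi, 1 split, the real one, gave as many as 13 genes (highest other 7), while 21 gave at least 5 lists (highest other 10). Without control replicate 2, 3 or 4 or mxl-2 RNAi replicate 2 or 3 the 13 calls became 1. Between the knockdowns, all 35 splits gave at least 0 genes, the highest other 269 with numbers 1 and 3 set against 2 and 4, again a structure by number. Among splits that part all 4 pairs as the real one does, the highest others were 0, 2, 1 and 3 genes in the same order. Since the numbers pair the libraries, the 35 splits do not stand in for chance, and only 8 part all pairs, too few for a share under 0.05. With the block the real split gave 12004, 60, 24 and 0 genes, and the highest other 0 in each case, so that 1, 1, 1 and 8 of the 8 splits gave as many as the real one.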
